A study of Homo sapiens with 8 samples.

How the data were processed

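RNA was measured on 8 Affymetrix human expression arrays from A375, a human melanoma cell line that carries an activating BRAF mutation. Per the labels' protocols, cells grew in RPMI1640 with 10% serum, were transfected with a nontargeting siRNA (siCont), an siRNA against BRAF (siBRAF) or an siRNA against ATF4 (siATF4), and were kept in normal or glutamine-free medium for 18 h, or in DMSO or 10 uM vemurafenib, a BRAF inhibitor, for 4 h. Biotin-labelled cRNA was made from 5 ug of total RNA isolated with a column kit, per the labels' protocols. Each of the 8 conditions has 1 array: siCont, siBRAF and siATF4 in normal medium, siCont and siBRAF in glutamine-free medium, siCont in DMSO, and siCont and siATF4 in vemurafenib.

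The deposited values are intensities on a linear scale, made by the authors with RMA (robust multi-array averaging), per the submitters' processing notes, with no version given in the sources used here. The table holds 54675 probe sets, of which 62 are array controls. The platform annotation pairs 41091 probe sets with 1 gene symbol, 1801 with several and 11721 with none. Genes were named from probe sets with exactly 1 symbol, which gave 19775 genes. No probe set is paired with BRAF in that annotation, so the level of BRAF itself was not analysed here and the siBRAF labels were not checked on their target.

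The arrays fell into 2 sets by scale. The 5 arrays of normal and glutamine-free medium had median intensities of 14.8 to 15.5, and the 3 arrays of DMSO and vemurafenib had medians of 36.4 to 36.9. The mean gap between sorted log2 values was 0.011 to 0.051 for the 13 pairs of arrays within a set and 0.95 to 0.97 for the 15 pairs across sets. Each difference was therefore taken within a set, and no gene level is set against a level of the other set. The comparison of the DMSO array with the siCont array in normal medium had been planned as a yardstick of the noise between control arrays. It gave 4662 genes at least 2-fold apart, 4641 of them higher in DMSO, and it was not used.

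Values were used as deposited, as log2(intensity + 1), so that a fold change is on the log2(value + 1) scale and understates the change of low genes. Each gene was represented by its probe set with the highest mean over the 8 arrays. A gene entered a comparison if the higher of its 2 values reached the median of all probe sets on that array (the 50th percentile). Genes at least 2-fold apart were counted. With 1 array per condition there are no replicates, so these differences have no replicate check and no p-value, and they describe pairs of arrays.

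For 3 effects a pair of comparisons with no array in common was available: glutamine-free medium in siCont and in siBRAF cells, siBRAF in both media, and siATF4 in normal medium and in vemurafenib. Genes at least 2-fold apart the same way in both pairs were counted beside the number expected if the lists were independent. An excess over that number is not by itself a test of a shared effect. The only test was an additive model fitted with limma 3.58.1 in R 4.3.3 to all 8 arrays, with terms for siBRAF, siATF4, glutamine-free medium, the DMSO and vemurafenib set, and vemurafenib, with an intensity trend in the variance and Benjamini-Hochberg adjustment at 0.05. It had 2 residual degrees of freedom, which are the departures from additivity of siBRAF across media and of siATF4 across settings. A call therefore means an estimated effect larger than these departures, not larger than the error between replicate cultures. The terms share 1 baseline, so an estimate is not the plain mean of its 2 pairs. With siATF4, TAC1 was estimated at -1.54, while its pairs were at -0.944 and -0.937. On simulated data for 14220 genes, an siBRAF effect of log2 size 1 was recovered in 0% of changed genes, of size 2 in 96.5% and of size 4 in 100%. For glutamine-free medium the shares were 45%, 99% and 100%, and for siATF4 31%, 98.5% and 100%. Each share comes from 1 simulated draw. The siBRAF and glutamine-free terms enter the design alike, so 0% against 45% is not a property of the design. The simulated effects were also additive, so the shares do not carry over to genes whose effect differs between backgrounds. In the real data ATF4 itself, at -2.32 with siATF4, was not called. The vemurafenib effect rests on 1 pair of arrays and has no residual.

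The 28 gene lists were fixed before the data were examined, as were the groups, the designs, the rule for named genes and the alternatives. The exception was quantile normalization of the comparison between the siCont arrays in DMSO and in normal medium, which was added after the scales were seen. They hold genes of the ATF4 and CHOP stress response, of serine, glycine, one-carbon, proline and asparagine synthesis, amino acid transporters, cytosolic aminoacyl-tRNA synthetases, glutamine metabolism, ERK pathway output, immediate early genes, melanocyte lineage, receptor kinases tied to BRAF inhibitor tolerance, S phase, G2 and mitosis, cholesterol synthesis, glycolysis, MondoA and ChREBP, hypoxia, ER chaperones, NRF2, autophagy and lysosome, p53, cell death, interferon response, ribosome biogenesis, heat shock and oxidative phosphorylation. Markers of keratinocytes, fibroblasts and blood cells and common reference genes complete them. Some lists share genes, so their counts are not separate evidence. FOS, EGR1, IER3 and MYC are on both the immediate early and ERK output lists. ATF3 is on the immediate early and the ATF4 and CHOP lists, and ASNS and CTH are on the latter and the amino acid synthesis list. The median of each list was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. The resulting percentile describes these arrays and is not a p-value.

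The rule for named genes took, in each direction, the 12 genes with the largest smaller difference of the 2 pairs for siBRAF, siATF4 and glutamine-free medium, the 12 with the largest difference for vemurafenib and the 8 with the largest difference between the glutamine responses, all at least 1.5-fold apart. ATF4 and the 4 members of each described list with the largest absolute difference were added, and genes with placeholder symbols were left out. Alternatives were median centring, quantile normalization over the 8 arrays, no level filter or a filter at the 75th percentile, the mean of all probe sets of a gene, leaving out probe sets marked as shared between transcripts, a threshold of 1.5-fold, log2(intensity + 16), and, for the additive model, no variance trend and leaving out each array. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. The number of arrays limits the precision of every value. No genome build was named in the sources used here, so no coordinates are given.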

Results

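Transcript levels were measured on 8 arrays of A375 melanoma cells, 1 per condition, to follow how BRAF and the stress transcription factor ATF4 shape the response to glutamine withdrawal and to the BRAF inhibitor vemurafenib. The first 5 arrays (siCont, siBRAF and siATF4 in normal medium, siCont and siBRAF without glutamine) had median intensities of 14.8 to 15.5. The other 3 (siCont in DMSO, siCont and siATF4 in vemurafenib) had medians of 36.4 to 36.9, and differences were taken only within these sets. All differences are log2 differences of single arrays without replicates, unless the additive model is named.

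ATF4 was lower on both arrays labelled siATF4. Its intensity was 534 with siATF4 against 1814 with siCont in normal medium, 3.4-fold lower, and 757 against 4548 in vemurafenib, 6.0-fold lower. ATF4 was also 2.4-fold higher in glutamine-free than in normal medium in siCont cells, at 4360, and 1.9-fold higher in vemurafenib than in DMSO, where it read 2390. In siBRAF cells it read 1519 in normal and 1498 in glutamine-free medium. After glutamine withdrawal, ATF4 was thus 2.91-fold lower with siBRAF than with siCont.

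**Figure D1:**
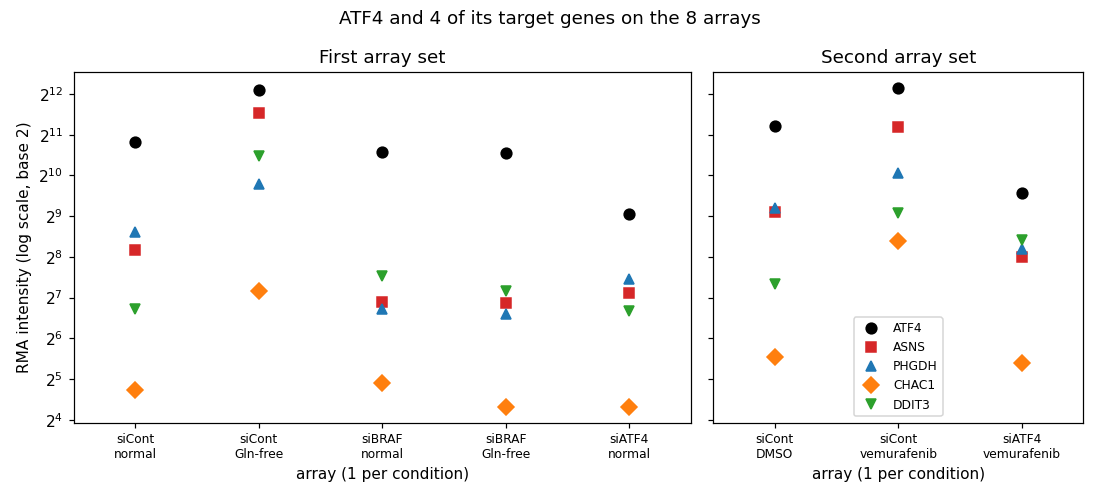
RMA intensity (y axis, log scale) of ATF4, ASNS, PHGDH, CHAC1 and DDIT3 on each array (x axis, 1 array per condition, 1 point per gene), in separate panels for the 2 array sets. ATF4 is highest without glutamine in siCont cells (4360) and in vemurafenib (4548), and ASNS stays at 118 and 117 in siBRAF cells with and without glutamine.

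Glutamine withdrawal for 18 h in siCont cells went with higher levels of stress response genes and lower levels of proliferation genes. ATF3 (difference 4.21) and SESN2 (3.90), which restrains growth signalling under amino acid shortage, stood among the highest of the ATF4 and CHOP genes. Of 27 such genes, 20 were at least 2-fold higher and 0 lower, with a median of 2.03, above all 10000 random lists. Asparagine synthetase ASNS (3.35), the folate enzyme ALDH1L2 (3.11) and cystathionine beta-synthase CBS (2.70) were among the 11 of 16 amino acid synthesis genes that were at least 2-fold higher, 1 being lower. Of 17 amino acid transporters 9 were higher, among them SLC3A2 (2.04), and 1 was lower, SLC1A1 (-2.29). Of 17 aminoacyl-tRNA synthetases 6 were higher, led by WARS1 (1.88) and SARS1 (1.80). Immediate early genes were higher in 17 of 21, with EGR1 at 5.14, JUN at 3.64 and MYC at 3.31. Of 33 ERK output genes 13 were higher, with LIF at 2.81, and 2 were lower. EGR1 and MYC are on both lists.

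Cell cycle genes were lower in the same cells. Of 40 S phase genes 19 were at least 2-fold lower and 0 higher, including the cyclin CCNE2 (-3.20) and POLE2 (-2.33), and of 33 mitotic genes 19 were lower and 0 higher, including KIF20A (-3.11) and CCNB1 (-1.84). Interferon-inducible genes were lower in 10 of 20, with IFIT1 at -2.61 and OAS1 at -1.99, sizes that depend on background because both lay below the array median without glutamine. Heat shock genes were lower in 4 of 13 (HSPB1 at -1.72). The actin control probes, a sign of RNA quality, read 0.28 higher at the 3' than at the 5' end on this array, against 0.16 on its siCont array in normal medium. In all, 769 genes were at least 2-fold higher and 964 lower among 13355.

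In siBRAF cells the same change of medium left nearly all genes within 2-fold. Only 6 genes were at least 2-fold higher and 10 lower among 13138, and the SD of the differences across genes was 0.19, against 0.72 in siCont cells. The ATF4 and CHOP genes had a median of 0.03 with 0 of 27 at least 2-fold apart, the immediate early genes a median of -0.01, the S phase genes 0.05 and the mitotic genes 0.01. The neuropeptide gene TAC1 (6.14 in siCont, 1.63 in siBRAF), the cytokine gene IL24 (5.25 and 1.36), FLG (3.03 and 1.40), GDA (1.65 and 1.06) and CYP1A1 (1.22 and 1.62), a target of the aryl hydrocarbon receptor, were higher in both pairs. TAC1 and FLG lay below the array median in siCont cells in normal medium, so the sizes of these differences depend on background. TIPARP, another target of that receptor, was at 1.33 and 0.78. The chemokine gene CXCL10 (-1.49 and -1.21) was lower in both, as were MX1 (-1.25 and -0.82) and IFI6 (-1.53 and -0.78), these by less than 2-fold in siBRAF cells. The interferon list had a median of -0.53 in siBRAF cells, with 4 of 24 at least 2-fold lower, below all random lists. Over 12780 genes, 5 were at least 2-fold higher in both pairs, against 0.33 expected for independent lists, and 1 was lower, against 0.29. The correlation across genes, which are not independent replicates, was 0.09.

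**Figure D2:**
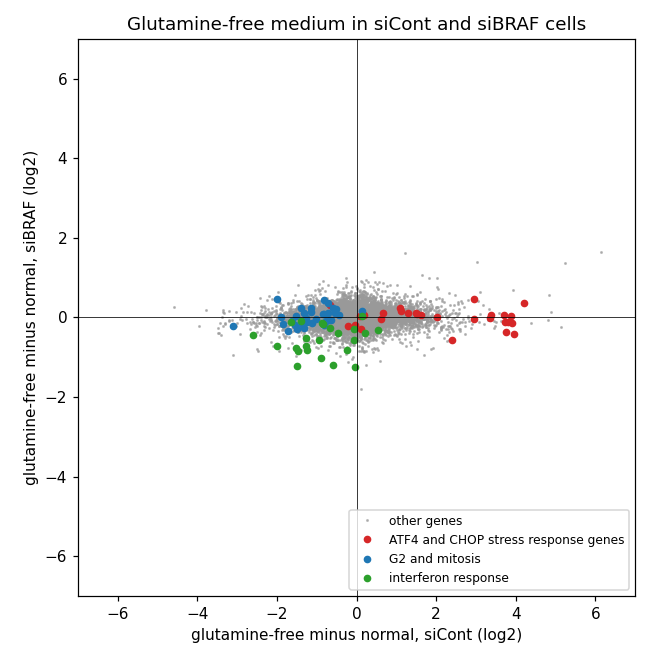
Log2 difference between glutamine-free and normal medium in siCont cells (x axis) and in siBRAF cells (y axis), 1 point per gene, with 3 gene lists in colour. ATF4 and CHOP genes spread to the right (median 2.03) and mitotic genes to the left (-1.14), while both stay near 0 on the y axis (0.03 and 0.01).

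The difference of the glutamine response between siBRAF and siCont cells was at least 2-fold for 1816 of 13713 genes, 1035 with a more positive and 781 with a more negative response in siBRAF cells. It was most negative for EGR1 (-5.38), RAB39B (-4.86), the cytokine genes TSLP (-4.74) and IL6 (-4.53), TAC1 (-4.50), the stress sensor ERN1 (-4.36), the immune checkpoint ligand CD274 (-4.26) and DDIT3, which encodes CHOP (-4.12). It was most positive for MEOX2 (4.85), TRIB2 (3.97), LRRC17 (3.74), DIXDC1 (3.56), B4GAT1 (3.51), B3GNT7 (3.45), NANOS1 (3.40) and CCNE2 (3.36), which were all lower without glutamine in siCont cells. MEOX2, LRRC17, DIXDC1, B3GNT7 and NANOS1 lay below the array median on the siCont glutamine-free array. RAB39B and TSLP lay below it on the other 3 of the 4 arrays, CD274 on both siBRAF arrays, IL6 on the siBRAF glutamine-free array and TAC1 on the siCont array in normal medium. The sizes and ranks of these 10 differences therefore depend on background and the added constant. The ATF4 and CHOP list had a median difference of -1.79, with 18 of 28 at least 2-fold, and the mitotic list one of 1.14, with 19 of 33. The difference rests on 4 arrays and was not tested.

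BRAF knockdown went with lower cell cycle and ERK output genes and with higher p53 and interferon genes. In normal medium all 33 mitotic genes were at least 2-fold lower with siBRAF, with a median of -2.78 and BUB1 at -3.38, and 27 of 33 were lower in glutamine-free medium, with a median of -1.75. In the additive model 30 of the 33 fell over all genes tested, and 31 when adjusted over the list alone. The topoisomerase TOP2A fell by 2.71 on the log2 scale (SE 0.26, limma adjusted p = 0.00778) and the proliferation marker MKI67 by 2.58 (SE 0.31, limma adjusted p = 0.0113). Of 40 S phase genes 18 fell and 0 rose, with 27 and 1 when adjusted over the list alone, and the list median was -1.79 in normal and -0.53 in glutamine-free medium.

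ERK output genes were at least 2-fold lower in 20 of 33 in normal and 24 of 33 in glutamine-free medium, with medians of -1.29 and -2.13, and 19 of the 33 fell in the additive model (25 when adjusted over the list alone). The ETS factors ETV4 and ETV5 fell by 3.60 and 3.39, and the feedback inhibitors SPRY4 and DUSP6 by 2.79 and 2.56. Other genes lowest in both pairs were the collagenase MMP1 (-4.14 in normal medium, -6.50 without glutamine), the integrin gene ITGB3 (-4.02 and -4.05), COL13A1 (-3.93 and -3.74), IL1RL1 (-3.70 and -6.07), the cytokine gene IL11 (-3.68 and -6.03), ADGRF1 (-3.64 and -3.75), TMEM158 (-3.47 and -4.41), CEMIP (-4.03 and -3.44), the ectonucleotidase NT5E (-3.42 and -4.44) and CD55 (-3.30 and -3.56). MMP1, IL1RL1 and ADGRF1 lay below the array median on both siBRAF arrays, and ITGB3 on the glutamine-free one, so the sizes of their differences depend on background. Ribosome biogenesis genes fell in 15 of 19 (17 when adjusted over the list alone), with medians of -0.83 and -0.92.

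The highest genes in both pairs were OLFML2A (5.42 in normal medium, 6.10 without glutamine), MOXD1 (5.37 and 6.40), GASK1B (5.28 and 7.13), the water channel AQP4 (5.22 and 5.48), CCN3 (5.13 and 6.35), the matrix gene POSTN (5.08 and 6.35), TRIM22 (5.03 and 5.22), SCRG1 (6.08 and 5.02), the cadherin CDH6 (5.33 and 4.95), the neurotrophin receptor NTRK2 (4.63 and 5.23), MATN2 (4.80 and 4.53) and MGP (4.52 and 6.27). AQP4, TRIM22, CDH6, NTRK2 and MATN2 lay below the array median on the siCont arrays of both pairs, with AQP4 at intensities of 2.8 and 2.6, and GASK1B and POSTN on the glutamine-free one. The sizes and ranks of their differences therefore depend on background and the added constant. For MATN2 in glutamine-free medium the sign was lost without probe sets shared between transcripts, at -0.064. All 12 rose in the additive model, and the 12 lowest genes named above all fell. They were picked for large differences in both pairs of the same arrays, so these calls are no separate support. p53 targets rose in 12 of 17 and fell in 0, also when adjusted over the list alone, with TP53INP1 at 3.94 and 3.99 and the cell cycle inhibitor CDKN1A at 2.60 and 1.71. Interferon genes rose in 18 of 24 (20 when adjusted over the list alone) and fell in 0, with IFI44L at 3.64 and 3.53 and IFIT1 at 2.20 and 4.37. These sizes too depend on background, since IFI44L lay below the array median on the siCont arrays of both pairs and IFIT1 on the glutamine-free one.

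ATF4 and CHOP genes depended on the medium: with siBRAF, 5 of 27 were at least 2-fold higher and 6 lower in normal medium (median 0.03), and 1 of 28 was higher and 18 lower in glutamine-free medium (median -1.86). Asparagine synthetase ASNS stood at -1.27 and -4.64 and TRIB3 at -1.03 and -4.03, while SESN3 was higher in both (4.65 and 4.48), from siCont values below the array median. Amino acid synthesis genes were lower in 8 of 16 and in 11 of 16, and 6 of 16 fell in the additive model (9 when adjusted over the list alone), among them PHGDH, the entry enzyme of serine synthesis, which fell by 2.58.

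In all, 955 genes were at least 2-fold higher and 1015 lower among 13346 in normal medium, and 1729 higher and 1464 lower among 13496 without glutamine. Of 13131 genes, 732 were higher in both pairs (122 expected for independent lists), 565 lower in both (106 expected) and 20 opposite, with a correlation across genes of 0.72. In the limma additive model 1737 of 14220 genes rose and 1546 fell with siBRAF at an adjusted p below 0.05. Its residual pools the siBRAF departures across media (SD 0.71) with the smaller siATF4 departures (SD 0.31), which do not measure siBRAF. The list calls above use this residual too. Without 1 of the siATF4 or vemurafenib arrays only the siBRAF departures remain, and fewer genes pass. This total of 3283 fell to 684 without the siATF4 array in normal medium, 696 without the siCont vemurafenib array, 689 without the siATF4 vemurafenib array and 1144 without the siCont array in normal medium. It reached 5411 without the siCont glutamine-free array, 6897 without the siBRAF array in normal medium and 5412 without the siBRAF glutamine-free array, where only the siATF4 departures remain as residual. The model called 0 genes for glutamine-free medium (774 at an unadjusted p below 0.05) and 0 for siATF4 (644). Without any effect a share of 0.05 of the 14220 genes would pass unadjusted, and both numbers are near that share. A response seen in siCont but not in siBRAF cells enters the model partly as a departure. The 0 for glutamine-free medium therefore does not mean that the medium had no effect. Nor does the 0 for siATF4 mean that it had none, since ATF4 itself, at -2.32, was not called. When adjusted over the list alone, 10 of 24 interferon genes fell with glutamine-free medium and the NRF2 target TXNRD1 rose. With siATF4, PHGDH and ALDH1L2 of 16 amino acid synthesis genes fell and TXNIP rose. No other list had a call for either term. This adjustment was made within each of the 28 lists and not across them, so calls of 1 or 2 genes can arise by chance. The siATF4 estimates are also not the means of their pairs, since arrays without siATF4 help set the baseline. Leaving out 1 siBRAF array, whichever it is, rests the glutamine-free term on 1 glutamine-free array, that of siCont. Only siATF4 departures then remain as residual, so calls from such a fit do not measure how the medium effect varies.

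**Figure D3:**
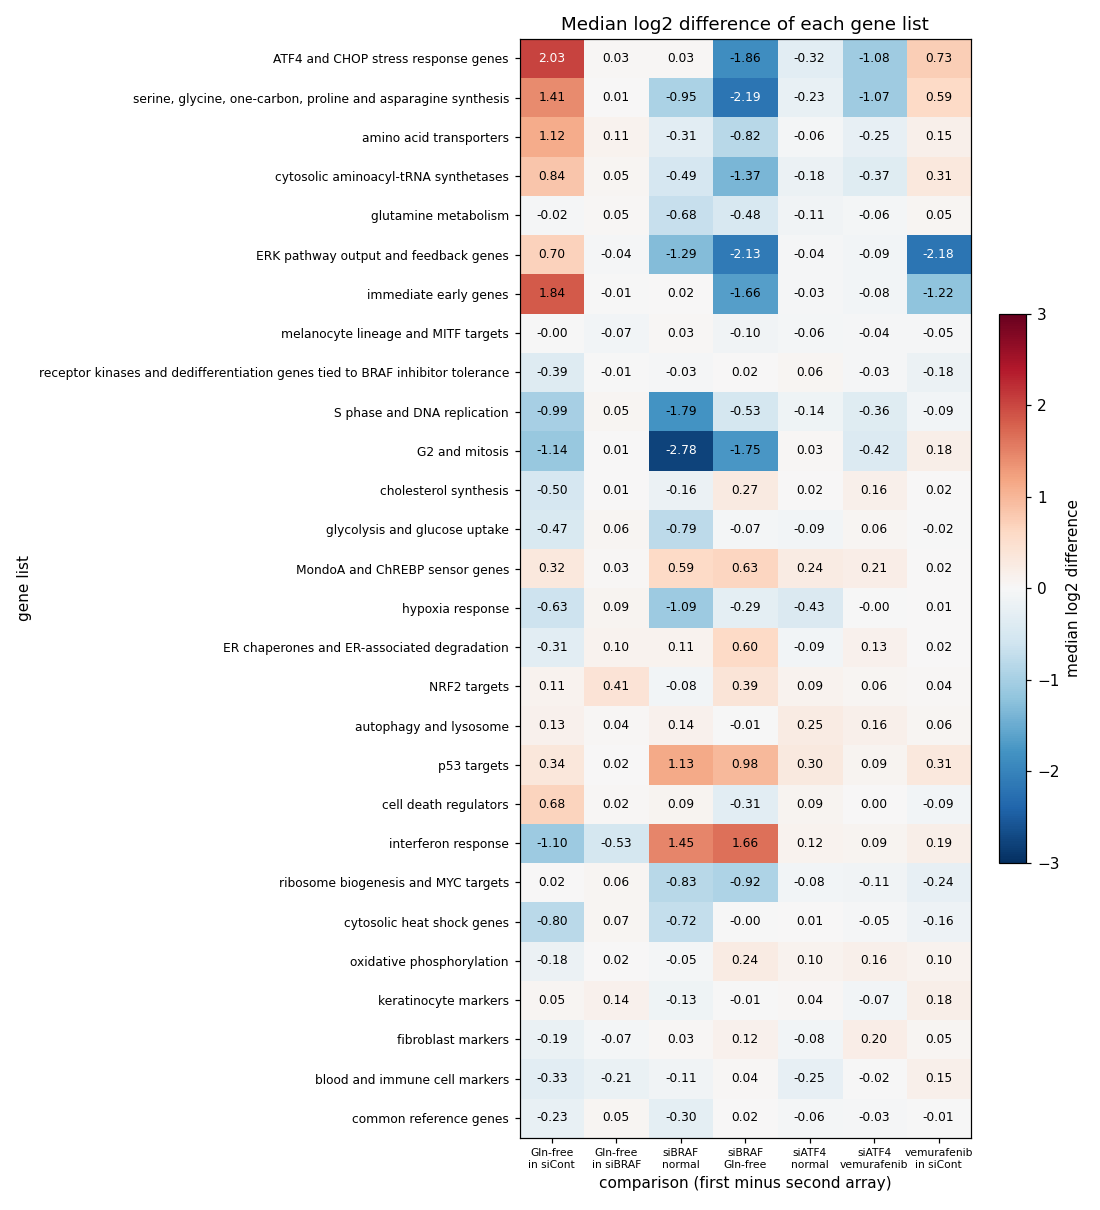
Median log2 difference of the 28 gene lists (rows) in the 7 comparisons of 2 arrays (columns), with the value printed in each cell and the colour scale from blue (lower) to red (higher). ATF4 and CHOP genes read 2.03 without glutamine in siCont cells, 0.03 in siBRAF cells and 0.73 in vemurafenib, and ERK output genes -2.18 in vemurafenib.

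ATF4 knockdown went with lower levels of a small set of amino acid synthesis genes, more so in vemurafenib than in normal medium in size, a difference that was not tested. The mitochondrial folate enzyme ALDH1L2 (-2.46 in normal medium, -3.22 in vemurafenib), CBS (-1.36 and -1.96), PHGDH (-1.14 and -1.86), the branched-chain aminotransferase BCAT1 (-1.14 and -1.18), the transcription factor JDP2 (-1.20 and -3.44), IGFBP3 (-1.12 and -1.35), FST (-1.14 and -1.06) and GPC6 (-1.01 and -1.25) were lower in both pairs. RAP1B, at -1.93 in vemurafenib, was 2-fold lower in normal medium. ASNS was at -1.05 and -3.18, and in normal medium its value without probe sets shared between transcripts was 0.068. TIMP3 was at -1.01 and -0.91. Higher in both were LY96 (1.70 and 1.33), CYP1A1 (1.28 and 1.17), the histone genes H2BC21 (1.44 and 1.16), H2AC6 (1.65 and 1.11) and H2BC4 (0.99 and 0.91), the hormone gene STC1 (1.78 and 1.12), VAV3 (1.12 and 1.33), LRRC17 (1.22 and 1.10), MAP2 (1.05 and 1.41), MSX2 (1.72 and 0.98) and PCDH7 (0.95 and 1.10). ALDH1L2 with siATF4 and LY96 and H2BC4 with siCont lay below the array median in both pairs, and JDP2 with siATF4 in normal medium, so the sizes of their differences depend on background. TMT1A was at 1.09 and 0.98, which became -0.014 and -0.063 without shared probe sets.

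As a group, the ATF4 and CHOP genes were at least 2-fold lower in 2 of 26 and higher in 1 in normal medium (median -0.32), and lower in 16 of 28 and higher in 0 in vemurafenib (median -1.08), both medians below all random lists. The 1 higher gene was the stress cytokine GDF15, at 2.21. Amino acid synthesis genes were lower in 4 of 16 and in 8 of 16, with 0 higher. In normal medium 62 genes were at least 2-fold higher and 51 lower among 13170, and in vemurafenib 27 were higher and 96 lower among 13173. Of 12589 genes, 8 were higher in both (0.09 expected for independent lists), 11 lower in both (0.33 expected) and 1 opposite, with a correlation across genes of 0.42. The 8 higher and 11 lower became 1 and 6 with log2(intensity + 16) and 2 and 8 with a filter at the 75th percentile. Most of the higher genes thus lay below that percentile in at least 1 pair. With the mean of all probe sets the counts became 5 and 7. The total of 113 in normal medium fell to 56 with log2(intensity + 16), so many of these genes lie at low levels. The 27 genes higher with siATF4 in vemurafenib became 8 with log2(intensity + 16), 12 with a filter at the 75th percentile, 17 with the mean of all probe sets and 43 under quantile normalization.

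Vemurafenib for 4 h went with lower ERK output genes and higher ATF4 target genes in siCont cells. The lowest genes were the ERK phosphatase DUSP6 (-6.76), SPRY2 (-4.41), MAFF (-3.98), IER3 (-3.94), the chemokine genes CXCL8 (-3.75) and CXCL1 (-3.38), TLR4 (-3.74), DUSP4 (-3.74), IL24 (-3.28), ANKRD1 (-3.25), TGFA (-3.16) and MYC (-3.14). DUSP6, CXCL8 (12.3), TLR4 (22.1), CXCL1 (27.0), ANKRD1 (33.3) and IL24 (35.4) had intensities below the array median in vemurafenib. The sizes and ranks of their differences therefore depend on background and the added constant. Of 33 ERK output genes 24 were at least 2-fold lower and 0 higher, with a median of -2.18, and of 21 immediate early genes 14 were lower and 1 was higher, the stress factor ATF3 at 1.57. Highest were INHBE (3.24), ECM2 (3.17), cystathionine gamma-lyase CTH (3.08), JDP2 (3.06), the thioredoxin-binding gene TXNIP (3.01), the transcription factor gene FOXD3 (2.94), STON1 (2.93), ST8SIA4 (2.83), the glutathione-degrading enzyme CHAC1 (2.81), CD24 (2.53) and RAB39B (2.37). The transcription factor gene SOX2 lay between TXNIP and FOXD3. INHBE, STON1 and RAB39B lay below the array median in DMSO, so the same holds for them. Of 28 ATF4 and CHOP genes 11 were at least 2-fold higher and 0 lower (median 0.73), and of 16 amino acid synthesis genes 6 were higher and 0 lower (median 0.59), with ALDH1L2 at 2.14 and ASNS at 2.08. Both medians lay above all random lists. Mitotic genes had a median of 0.18 and S phase genes one of -0.09, with 0 of 33 and 0 of 40 at least 2-fold apart. In all, 113 genes were at least 2-fold higher and 253 lower among 13160.

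With siATF4, the median of the ATF4 and CHOP genes in vemurafenib lay below their level in DMSO, although 3 genes stayed at least 2-fold above it. The median of the 28 genes against the siCont DMSO array was -0.33 with siATF4, against 0.73 with siCont, and 24 of the 28 were lower with siATF4 than with siCont in vemurafenib. Of the 11 genes that were at least 2-fold higher in vemurafenib with siCont, 8 were less than 2-fold higher than in DMSO with siATF4, and 5 were below it. The other 3 were SESN3 (2.22), CTH (1.21) and DDIT3 (1.09), all against DMSO. INHBE (-3.67), CHAC1 (-2.96) and CTH (-1.88) were lower with siATF4 than with siCont in vemurafenib, while DDIT3 was at -0.66. INHBE with siATF4 in vemurafenib and SESN3 in DMSO lay below the array median, so the sizes of their differences depend on background. For amino acid synthesis genes the medians were 0.59 and -0.25. ERK output genes kept a median of -1.98 against DMSO. The siCont DMSO array enters both medians. The 11 genes were chosen for high values on the siCont vemurafenib array, which favours lower values with siATF4 for them. siATF4 in DMSO was not analysed here, so an effect of siATF4 without drug is not subtracted.

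Many genes differed the same way with vemurafenib and with siBRAF, on arrays with none in common. Among 12608 genes, 60 were at least 2-fold higher with both (6.55 expected for independent lists) and 137 lower with both (19.7 expected) in normal medium. In glutamine-free medium the numbers were 60 (13.3 expected) and 142 (27.7 expected). In normal medium 5 genes were higher with vemurafenib and lower with siBRAF (8.51 expected) and 9 the other way (15.2 expected). In glutamine-free medium these were 23, more than expected for independent lists, and 18, fewer than the 30.7 expected. TXNIP was at 3.01 with vemurafenib and 3.73 with siBRAF in normal medium, FOXD3 at 2.94 and 3.19, STON1 at 2.93 and 3.40, DUSP6 at -6.76 and -2.13, and ETV5 at -2.87 and -3.23. The correlation across genes was 0.39 in normal and 0.34 in glutamine-free medium. Against glutamine-free medium in siCont cells it was -0.07. There 31 genes were higher with both (5.59 expected) and 49 lower with both (18.9 expected). Another 70 were lower with vemurafenib and higher without glutamine (14.1 expected), and 22 the other way (7.48 expected). Every direction thus exceeded its expected number, so an excess over independent lists does not by itself show a shared response. INHBE (3.38), CTH (3.87) and CHAC1 (2.39) were higher without glutamine as with vemurafenib, and MYC (3.31) and SPRY2 (1.30) were higher without glutamine and lower with vemurafenib. INHBE lay below the array median in siCont cells in normal medium and in DMSO, STON1 in DMSO and DUSP6 in vemurafenib, so the sizes of these differences depend on background.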

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

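The tests of the interferon genes and of the weak glutamine response in siBRAF cells were chosen after the results were seen. The test of the 2 array sets was written before its result but after the scales were seen. Differences between groups in this part rest on single arrays and were not tested.

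Some named genes went opposite ways, by at least 1.5-fold each, in the 2 backgrounds of an effect. For glutamine-free medium, the difference (siBRAF minus siCont) was 1.51 for AKR1B10, -2.06 for BIK, -2.64 for CXCL8 and 2.60 for LUM. For siBRAF, 8 of these genes were higher in normal and lower in glutamine-free medium, with differences (glutamine-free minus normal) of -4.12 for DDIT3, -5.38 for EGR1, -3.31 for GADD45A, -3.91 for NUPR1, -4.03 for SESN2, -1.80 for KLF4, -1.44 for GABARAPL1 and -2.90 for BCL2A1. The opposite held for ALDOC (2.33), B3GNT7 (3.45), B4GAT1 (3.51), CCNE2 (3.36), CSGALNACT1 (1.63), MEOX2 (4.85), NANOS1 (3.40), P4HA1 (1.49), PCNA (1.84) and TRIB2 (3.97). The differences for glutamine-free medium and for siBRAF are the same contrast as the difference of glutamine responses above, so they are no separate result. With the medium, DDIT3 moved by -0.37 in siBRAF and 3.75 in siCont cells, and MEOX2 by 0.27 and -4.58. For siATF4, the difference (vemurafenib minus normal medium) was 2.43 for CEMIP, -1.80 for ECM2, 2.13 for FDCSP, 2.25 for MGP and -2.37 for PMAIP1. AKR1B10, LUM, B3GNT7, MEOX2 and NANOS1 lay below the array median on the siCont glutamine-free array and FDCSP on the siCont vemurafenib array, so the sizes of their differences depend on background.

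Probe sets paired with no gene symbol, which enter no comparison of the report, also differed. Those with several symbols were not counted here. Of those without a symbol, 276 were at least 2-fold apart between siBRAF and siCont in normal and 449 in glutamine-free medium. Between vemurafenib and DMSO 44 were apart. With the medium 259 were apart in siCont and 3 in siBRAF cells, and with siATF4 17 in normal medium and 15 in vemurafenib.

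Only 16 genes differed at least 2-fold with the medium in siBRAF cells, against 1733 in siCont cells. Whether the siBRAF glutamine-free array holds cells kept in normal medium cannot be decided here. At least 2-fold apart the same way in both pairs were 6 genes, where 0.62 are expected for independent lists. In siBRAF cells, the genes higher in siCont cells had a median of 0.0279, at percentile 98.1 and just above the random limit of 0.0271. Those lower in siCont cells had a median of -0.01, below all random lists, so both medians were small. Genes that vary between cultures in the same medium can overlap in this way too, and no replicate shows how many do. That the ATF4 and CHOP genes were already at their glutamine-free level in siBRAF cells is argued against by a median of -1.82 between siBRAF in normal medium and siCont without glutamine. The mitotic genes were already below that level, with a median of -1.64, so for them a floor stays open. Cells kept in normal medium, a weaker deprivation of that culture and a response that needs BRAF all remain open. No marker of glutamine supply independent of them was among the lists.

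The siCont arrays in DMSO and in normal medium differed at least 2-fold in 4662 genes. Quantile normalization over the 8 arrays, an alternative added after the scales were seen, left 417. It removes a shift of scale whatever its source, so separate normalization of the 2 array sets cannot be told apart from other sources of the shift. Vehicle, time in culture and batch cannot be told apart for these 417 genes, since each set holds its own conditions.

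Interferon genes were higher with siBRAF, with a median of 1.45 in normal and 1.66 in glutamine-free medium. A response shared by every siRNA, the nontargeting one included, would cancel in these differences, so they cannot test for it. With siATF4 in normal medium the median was 0.12, so a rise of that size was not seen with the other targeting siRNA. An interferon response to the siBRAF duplex itself and an effect of lost BRAF signalling cannot be told apart: the median after vemurafenib, which acts without an siRNA, was 0.19, at percentile 98.8 of random lists but far below that with siBRAF, and the drug acted for only 4 h.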

How the results depend on the processing

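The labels share no numbered replicates: No paired analysis was possible because each group has 1 array. Swapping the DMSO and normal-medium controls, and counting DMSO as normal medium in the additive model, were not run, because these arrays lie in sets of different scale. Under median centring and quantile normalization every total at least 2-fold in a pair of arrays or in both pairs stayed within 1.5 times its value, as did each of these totals without a level filter or without probe sets shared between transcripts. By direction, 27 higher with siATF4 in vemurafenib became 43 under quantile normalization. Without shared probe sets 10 lower with glutamine-free medium in siBRAF cells became 6, 5 higher in both pairs of glutamine-free medium became 3, and 8 higher in both pairs of siATF4 became 5. ATF4 levels, medians of the ATF4 and amino acid synthesis lists in vemurafenib, the total for the difference of glutamine responses and correlations with vemurafenib held under each alternative run for them. For that difference these were only median centring and the mean of all probe sets. The mean could not move the ATF4 level, which was read by 1 probe set. Shifting a whole array by median centring leaves a correlation as it is. With a threshold of 1.5-fold the counts were larger by construction: 4009 for glutamine-free medium in siCont and 170 in siBRAF cells, 4201 for siBRAF in normal and 5782 in glutamine-free medium, 590 for siATF4 in normal medium and 571 in vemurafenib, and 1020 for vemurafenib. In both pairs they were 51 for glutamine-free medium, 2838 for siBRAF and 137 for siATF4. With a filter at the 75th percentile the counts were 10 for glutamine-free medium in siBRAF cells, 68 for siATF4 in normal medium and 10 for siATF4 in both pairs. With log2(intensity + 16) they were 9, 56 and 7, and 3 for glutamine-free medium in both pairs. With the mean of all probe sets they were 71 for siATF4 in normal medium and 12 in both pairs. The 8 higher and 11 lower in both pairs of siATF4 became 2 and 8, 5 and 7, and 1 and 6 with the 75th percentile, the mean and log2(intensity + 16). Where totals held, directions still moved: 113 higher with vemurafenib became 75 with the 75th percentile and 70 with the mean of probe sets. The 964 lower with glutamine-free medium in siCont cells became 633 with that mean and 630 with log2(intensity + 16), and 1035 higher in the difference of glutamine responses became 671 with the mean. The 27 became 12, 17 and 8 under these 3 settings. The 1 gene lower in both pairs of glutamine-free medium became 0 with the 75th percentile. The cause was not tested beyond fewer genes passing the filter. In the additive model, leaving out each array gave 684 to 6897 genes for siBRAF, 0 to 5068 for glutamine-free medium and 0 to 0 for siATF4; a lone array is then assumed to vary like the others.

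Of 1326 values of named genes and lists under alternatives, 1194 held, 126 moved by at least 1.5-fold and 6 changed sign, all 6 without probe sets shared between transcripts; the cause was not tested. These were MATN2 for siBRAF in glutamine-free medium (-0.064), TMT1A for siATF4 in normal medium (-0.014) and vemurafenib (-0.063), ASNS for siATF4 in normal medium (0.068), the MondoA list for siATF4 in normal medium (-0.0063) and the NRF2 list for siBRAF in glutamine-free medium (-0.091). Signal over background limits genes near the array medians of 14.8 to 36.9, where the added constant shrinks a difference.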

Other observations

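Gene groups not described above also differed. The NRF2 targets were higher without glutamine in siBRAF cells, with a median of 0.41, above all random lists, and HMOX1 at 0.87, GCLM at 0.83, TXNRD1 at 0.82 and NQO1 at 0.80. None of the 18 was at least 2-fold apart, and in siCont cells the median was 0.11. The glucose-sensing MondoA and ChREBP genes TXNIP (3.73 in normal medium, 3.23 without glutamine) and ARRDC4 (2.89 and 2.72) were higher with siBRAF, and in vemurafenib they were at 3.01 and 1.62. Of the 6 genes on that list 3 rose with siBRAF in the limma additive model. Hypoxia genes were at least 2-fold lower with siBRAF in normal medium in 8 of 15 and higher in 1 (median -1.09), with PDK1 at -2.10 and NDRG1 at -1.97, and glycolysis genes were lower in 8 of 22 (median -0.79), with HK2 at -1.93 and SLC2A3 at -1.81. In glutamine-free medium 5 of 15 hypoxia genes were lower with siBRAF and 1 was higher (median -0.29), and 3 of 22 glycolysis genes were lower (median -0.07), at percentiles 12.3 and 36.4 of random lists. In vemurafenib the glycolysis median was -0.02 with SLC2A3 at -1.92.

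In vemurafenib, all 33 mitotic genes were lower with siATF4 than with siCont, with a median of -0.42, and 38 of 40 S phase genes were lower, with a median of -0.36. None of the mitotic genes and 1 S phase gene reached 2-fold, and in normal medium the medians were 0.03 and -0.14. VEGFA was at -2.16 with siATF4 in vemurafenib and at -0.35 in normal medium. Cell death regulators were at least 2-fold higher in 5 of 16 without glutamine in siCont cells, among them PMAIP1 (2.05) and BCL2A1 (2.33), and PMAIP1 was at -4.31 with siBRAF without glutamine. Melanocyte lineage genes had medians from -0.10 to 0.03 in the 7 comparisons, with GPNMB at 2.61 and 2.97 with siBRAF in the 2 media. Among receptor kinase and tolerance genes, NGFR was at 3.14 and 3.64 with siBRAF, and EGFR at -1.25 with vemurafenib (list median -0.18).

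Other lists gave the following medians. Glutamine metabolism was at -0.02 without glutamine in siCont cells and -0.68 with siBRAF in normal medium, with CTPS1 at -1.21, and -0.48 with siBRAF without glutamine. Cholesterol synthesis was at -0.50 without glutamine in siCont cells, with HSD17B7 at -1.40. ER chaperones were at -0.31 there and at 0.60 with siBRAF without glutamine, with CALR at 1.51, and at 0.11 with siBRAF in normal medium. Autophagy and lysosome genes were at 0.25 with siATF4 in normal medium and 0.16 in vemurafenib, with 0 of 23 at least 2-fold apart in either. Oxidative phosphorylation genes stayed within 2-fold in all 7 comparisons, with medians from -0.18 to 0.24. Common reference genes ran from -0.30 to 0.05, with HPRT1 at -1.22 without glutamine in siCont cells and at -1.30 with siBRAF in normal medium. Blood cell markers ran from -0.33 to 0.15 and keratinocyte markers from -0.13 to 0.18. Fibroblast markers ran from -0.19 to 0.20, with POSTN at 5.08, LUM at 2.25 and COL6A3 at -2.51 with siBRAF in normal medium, the last from a siBRAF value below the array median.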
